A study of Mus musculus with 14 samples.

How the data were processed

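RNA-seq values were taken as deposited. The authors gave them as FPKM, fragments per kilobase of transcript per megaread mapped, made before deposit with CASAVA, TopHat2, Cufflinks and Cuffdiff against build mm9 according to the submitters' processing notes, with no versions given. Per the labels the RNA was polyadenylated, with libraries from a directional kit. H3K36me3 ChIP-seq came as 1 deposited peak list per sample, with a score for every peak made by the authors and a lowest score of 50. The submitters' processing notes name CASAVA, Bowtie and bedtools for ChIP-seq, and the peaks carry MACS names, so they were called with MACS, version not given. Spike-in chromatin was added per the labels, but whether the lists were scaled by it is not stated in the sources used here. The input libraries, listed for PD WT and PD Setd2KO but not for RS, were not analysed here. Whether they served in peak calling is not stated in those sources.

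Each table held 20626 genes. Whole read numbers were recovered from the FPKM values with a tolerance of 0.003, which held for 94.9% of 145531 values above 0 and for 0 of 500 scrambled control genes. They gave the depth of each library. Intervals differed between tables for 1056 genes (5.12%), and among those named here were Arc, Fam89b, Dcn, Rnls, Mybl1, Gsn, Catsper3, Dnmt3b and Akr1cl. All 8 values were shared with another gene for 265 genes. Of the genes tested, 10481 had 1 length in all tables.

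Genes with a mean of at least 1 FPKM in at least 1 of the 4 groups were kept, and log2(FPKM + 1), with a pseudocount of 1 FPKM, was fitted with limma with an intensity trend, with 1 mean per group in a single fit. Contrasts were Setd2KO against WT in PD and in RS, RS against PD in each genotype, and the difference between the Setd2KO effects in RS and PD. P-values were adjusted with the Benjamini-Hochberg method over all tested genes of a contrast, and genes with adjusted p under 0.05 were called. The moderated tests had 4 residual and 6.92 prior degrees of freedom. Changes in PD, between cell types and between effects are given relative to the all-gene median where said, and their p-values are those of the test against 0 on the deposited scale.

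Gene lists and the named-gene rule were fixed before the data were examined. The lists were protamines and transition proteins, acrosome, histone to protamine exchange, post-meiotic transcription and mRNA storage regulators, sperm flagellum, sperm glycolysis, CatSper and sperm ion channels, manchette and head shaping, sperm-egg binding and fusion, multicopy sex-linked spermatid genes, synaptonemal complex and meiotic recombination, meiotic division, piRNA pathway, H3K36 methylation writers, erasers and readers, p53 targets and apoptosis, unfolded protein and integrated stress response, immediate early and heat shock, interferon response, and housekeeping. Marker lists were spermatogonia, elongating and condensing spermatids, Sertoli cells, Leydig cells, peritubular myoid cells, macrophages, and erythrocytes and endothelium. Members were written from general knowledge and matched to symbols of the tables directly or through RefSeq synonyms, and Sept12, Dcst2, Ssty1, Ssty2, Sly, Mgclh, Gmcl1l, Rbmy1a1, Rnf212 and Rhox5 had no match. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with p-values adjusted over the lists of a contrast. Called members were counted on p-values adjusted over all genes and again adjusted over the list alone.

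Genes were named by rule. Setd2, Acrbp, Prm1, Prm2, Tnp1 and Tnp2 were always named. Next came the 10 largest changes per direction in PD and in RS with adjusted p under 0.05, both Setd2KO libraries on the same side of both WT libraries and at least 5 FPKM in the higher group. Then came list members with the largest changes, up to 4 where camera called the list and fewer elsewhere, and the 5 largest per direction for RS against PD in WT and for the difference between effects. Peaks were named over the genes always named, over the 5 genes with the longest WT cover per cell type, and for the 3 longest Setd2KO peaks per cell type. Genes known only by clone or model number took their place in the ranking but are not printed, among them BC061237.

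Peaks were compared by number, covered bases and overlap of at least 1 base, with exact 95% binomial intervals and with the peaks of the first list placed at random on their own autosomes in 20 draws, within the extent of each chromosome seen in the data. A peak was assigned to each gene it overlapped by at least 1 base, and a gene lost its peak when it had WT cover and no Setd2KO cover. Random gene sets were matched on mean expression and drawn from all tested genes. Cover along the gene body was averaged over autosomal genes of at least 10 kb. Correlations between contrasts were set beside 100 simulated draws. These had no Setd2KO effect in RS for the pair that shares the RS WT libraries, and none in either cell type for the pair that shares no library.

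Alternatives fixed in advance were a pseudocount of 0.1 FPKM, no filter, a filter at 5 FPKM, upper-quartile scaling, quantile normalization, an added 2-fold threshold, limma without the trend, only the compared groups in the fit, the replicate number as a block (see the sensitivity values), each library left out in turn, camera with an estimated correlation, peaks of at least 1000 bases, the 50% of peaks with the highest scores, merged peaks, overlap of 50%, and cover of at least 20% of a gene. Added after the data were seen were voom on the recovered reads, genes of 1 length only, the first Setd2KO library of each cell type left out, the other cell type subtracted at its estimated share (with no value left negative), and random sets of autosomal genes only.

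The code was also tested on simulated data with known changes. Of genes changed 1.5-fold, 2-fold and 4-fold, 35.8%, 95.5% and 100% were recovered in a PD contrast, with 11 false among 165 calls, and 31.3%, 86.6% and 100% in an RS contrast, with 8 false among 153. Camera called 0 of 20 unchanged lists and the raised list. The share of spermatid-specific transcripts, taken against RS Setd2KO, read 12.5% and 13.6% after 10% of RS Setd2KO was added to PD WT libraries. Taken against RS WT, those libraries had read 1.92% and 2.77%. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, bedtools 2.31.1, R 4.3.3 and limma 3.58.1. Reads were not aligned again, so transcripts, splicing and the deleted part of Setd2 were not examined.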

Results

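Polyadenylated RNA and H3K36me3, the histone mark that the methyltransferase Setd2 places over transcribed gene bodies, were measured in male germ cells of adult C57BL/6J mice. Cells had been sorted by flow cytometry on Hoechst and propidium iodide staining into pachytene and diplotene spermatocytes (PD), which are in meiotic prophase, and round spermatids (RS), the haploid cells that follow meiosis. Each cell type came from wild-type (WT) mice and from mice labelled Setd2KO. RNA-seq comprised 2 libraries in each of the 4 groups, and H3K36me3 ChIP-seq comprised 1 peak list per group. RNA-seq depth, worked back from the deposited FPKM values, in megareads was 51.1 and 51.7 in PD WT, 61.9 and 69.4 in PD Setd2KO, 84.9 and 50.8 in RS WT, and 58.0 and 66.0 in RS Setd2KO. Reads in genes made up 43.5% of the total in the first PD WT library and 46.8% to 51.7% in the other libraries. At these depths 1 read per kilobase was worth 0.0118 to 0.0197 FPKM. Replicates correlated across genes at r = 0.992 to 0.995. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

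Setd2 itself (chromosome 9, 110435101 to 110521137, plus strand, mm9) was read first, because it is the targeted gene. In PD it stood at 21.2 and 19.1 FPKM in the WT libraries and at 21.03 and 21.4 FPKM in the Setd2KO libraries. In RS it stood at 5.24 and 5.58 FPKM in WT and at 12.1 and 8.67 FPKM in Setd2KO. The RS difference passed the test, with a log2 change of 0.81 (limma, adjusted p = 0.00162), and the PD difference did not (adjusted p = 0.736). The labels do not say which part of Setd2 was deleted, and a value over the whole gene model does not check a deletion. The genotype of every RNA-seq library is therefore as labelled, and so is the direction of each difference below.

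The peak lists address whether the mark depends on Setd2 in both cell types. H3K36me3 peaks covered 238 megabases in PD WT and 229.9 megabases in RS WT, against 0.701 megabases in PD Setd2KO and 0.650 megabases in RS Setd2KO. Acrbp (chromosome 6, 124999945 to 125004211), whose product binds proacrosin in the acrosome, lay wholly inside a PD WT peak from 124999817 to 125010609 and an RS WT peak from 124989912 to 125005776. Prm1 (chromosome 16, 10796425 to 10796916) and Prm2 (10791470 to 10792198), which encode the protamines that package sperm DNA, lay inside separate PD WT peaks and together under 1 RS WT peak from 10790979 to 10801706. The transition protein gene Tnp2 was covered over its whole length in PD WT and 6.52% in RS WT, Prm3 over 28.0% and 7.13%, and Tnp1 had no peak in any list. Setd2 was covered over 99.8% of its length in PD WT and had no peak in RS WT. No Setd2KO peak lay over any of these genes.

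The WT lists held 44358 peaks in PD and 34499 in RS, with median widths of 2822 and 3278 bases. The Setd2KO lists held 1152 and 3692 peaks, with median widths of 587 and 176 bases. In covered length the WT list exceeded the Setd2KO list 340.0 times in PD and 354 times in RS. A Setd2KO peak touched 68 of the PD WT peaks (0.153%, exact 95% interval 0.119% to 0.194%) and 305 of the RS WT peaks (0.884%, 0.788% to 0.989%). When the WT peaks were placed at random on their chromosomes, 0.267% and 0.98% were touched. The longest WT cover in both cell types was over Tbc1d5, a Rab GTPase regulator, with 387 kb in PD and 389 kb in RS. In PD it was followed by Bbs9 (286 kb), Cep128 (281 kb), Nbea (273 kb) and Nbas (273 kb), and in RS by Nbea (327 kb), Bbs9 (321 kb), Cep128 (308 kb) and Spag16 (291 kb). The longest PD Setd2KO peaks were 1940 bases over Kif2b (chromosome 11, 91436826 to 91438765), 1614 bases over Fzr1 (chromosome 10, 80832842 to 80834455), the last wholly inside a WT peak, and 1526 bases over Tmco5 (chromosome 2, 116704536 to 116706061). In RS Setd2KO they were 1139 bases outside genes (chromosome 2, 98506388 to 98507526), 775 bases outside genes but wholly inside a WT peak (chromosome 11, 88829541 to 88830315) and 569 bases over Fasl (chromosome 1, 163711638 to 163712206). With 1 library per group these differences have no replicate check, the ChIP depth is unknown, and the intervals cover counting error only. The authors' score was under 60 for 74.1% and 68.1% of the Setd2KO peaks against 7.62% and 7.32% of the WT peaks, and the shortest RS Setd2KO peak (76 bases) was shorter than any peak of the other lists (286 bases or more).

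WT peaks of both cell types lay over largely shared regions. Of the PD WT peaks, 86.5% touched an RS WT peak, and of the RS WT peaks 80.7% touched a PD WT peak, against 12.6% and 13.6% for peaks placed at random. Within autosomal genes of at least 5 FPKM and at least 10 kb (4031 in PD and 3732 in RS), mean cover in PD WT went from 62.0% in the first of 10 bins of the gene body to 82.9% in the last, and in RS WT from 54.3% to 63.4%. Cover of the same genes in PD Setd2KO was at most 0.055% in any bin. Autosomal genes with a PD WT peak had a median of 7.28 FPKM against 0.0326 FPKM for those without, and in RS the medians were 4.68 and 0.0875 FPKM. At least 1 FPKM was reached by 87.0% of genes with a peak and 10.1% of those without in PD, and by 77.2% and 20.7% in RS.

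**Figure D1:**
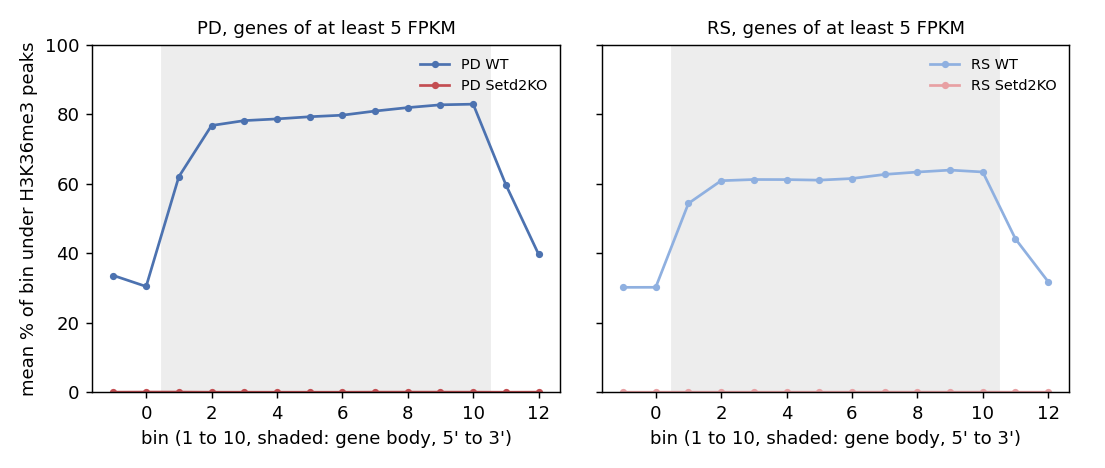
Mean share of each bin under H3K36me3 peaks (y axis, percent) along autosomal genes of at least 5 FPKM and at least 10 kb, with bins 1 to 10 from the 5′ to the 3′ end of the gene body and flanking bins on either side (x axis). WT cover (1 library each) rises to 82.9% in the last body bin in PD and 63.4% in RS. The Setd2KO lines lie near 0, with at most 0.055% in any bin in PD and 0.031% in RS.

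The X and Y chromosomes carried no peak in either WT list. In RS WT 169 X-linked genes reached at least 5 FPKM and none had a peak, with an exact 95% limit of 2.16%, whereas 79.5% of autosomal genes at that level had 1. In PD WT, where the X is transcriptionally silenced, 16 X-linked genes reached 1 FPKM and none had a peak (exact 95% limit 20.6%), against 12.71 expected at the autosomal share. Among 290 X-linked genes of 0.1 to 1 FPKM there was also none (limit 1.26%), against 28.5% of autosomal genes. The RS Setd2KO list held 13 X peaks and 3 Y peaks, and the PD Setd2KO list held 0.

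**Figure D2:**
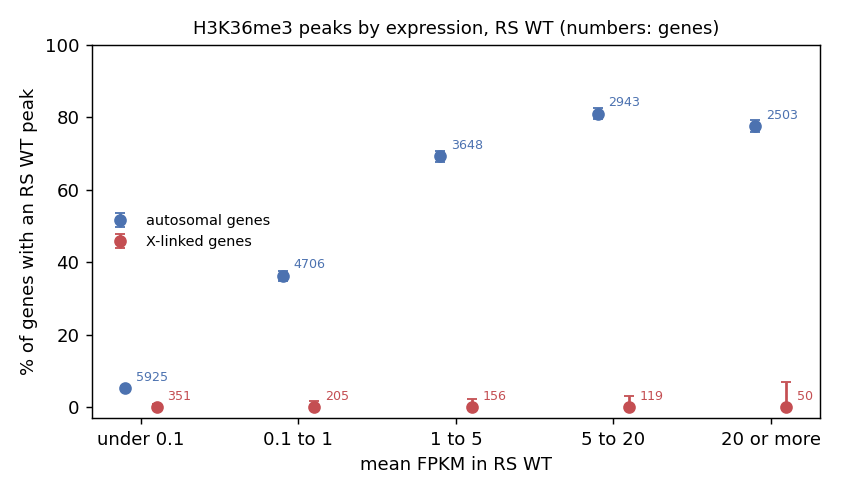
Share of genes with an RS WT peak (y axis, percent, with exact 95% intervals) by mean FPKM in RS WT (x axis), for autosomal and X-linked genes, with the number of genes beside each point. The autosomal share goes from 5.32% under 0.1 FPKM to 77.6% at 20 FPKM or more, and the X-linked share is 0 in every class.

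Acrbp and the protamine genes, which the series title names, were lower in RS Setd2KO, and Acrbp, Prm1 and Prm2 were lower in the PD Setd2KO libraries as well. In PD, Acrbp stood at 172 ± 28.0 FPKM in WT and 74.3 ± 3.23 FPKM in Setd2KO (mean ± SD, n = 2 throughout), and in RS at 297 ± 19.3 and 198 ± 11.5 FPKM. Prm1 stood at 927 ± 20.6 FPKM in RS WT and 228 ± 13.3 FPKM in RS Setd2KO, and Prm2 at 929.8 ± 117 and 233 ± 15.4 FPKM. The transition protein genes Tnp1 and Tnp2, whose products replace histones before the protamines do, stood at 1007 ± 83.8 and 1000.1 ± 94.9 FPKM in RS WT and at 293 ± 13.8 and 292 ± 13.7 FPKM in RS Setd2KO. In RS the log2 changes were −0.58 for Acrbp (limma, adjusted p = 0.0147), −2.02 for Prm1 (1.19e-05), −1.99 for Prm2 (4.11e-05), −1.78 for Tnp1 (4.58e-05), −1.77 for Tnp2 (3.82e-05) and −0.86 for Prm3 (0.00844). In PD the changes relative to the all-gene median were −1.38 for Acrbp (adjusted p = 0.000612), −0.99 for Prm1 (0.00597) and −1.38 for Prm2 (0.00197). Prm3 rose in PD, by 0.80 relative to that median (0.00548), from 4.04 to 9.38 FPKM, but its direction was not settled, because with the other cell type subtracted its change was −0.08 (0.889). Tnp1 (−0.68, 0.0691) and Tnp2 (−0.60, 0.112) did not pass in PD. In the PD Setd2KO libraries the median of Prm1, Prm2, Tnp1 and Tnp2 was 11.3% and 7.77% of the RS Setd2KO level. Genes specific to round spermatids, described below, stood at 13.1% and 7.67%, so the PD Setd2KO level of these late genes cannot be told apart from spermatid RNA. The fall of Acrbp in RS was lost without the first or the second Setd2KO library or the first WT library (adjusted p = 0.129, 0.0562 and 0.109), that of Prm3 without the first Setd2KO or the first WT library (0.0645 and 0.0607), that of Prm1 in PD without the second Setd2KO library (0.114), and the rise of Prm3 in PD without the first Setd2KO library (0.0507).

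**Figure D3:**
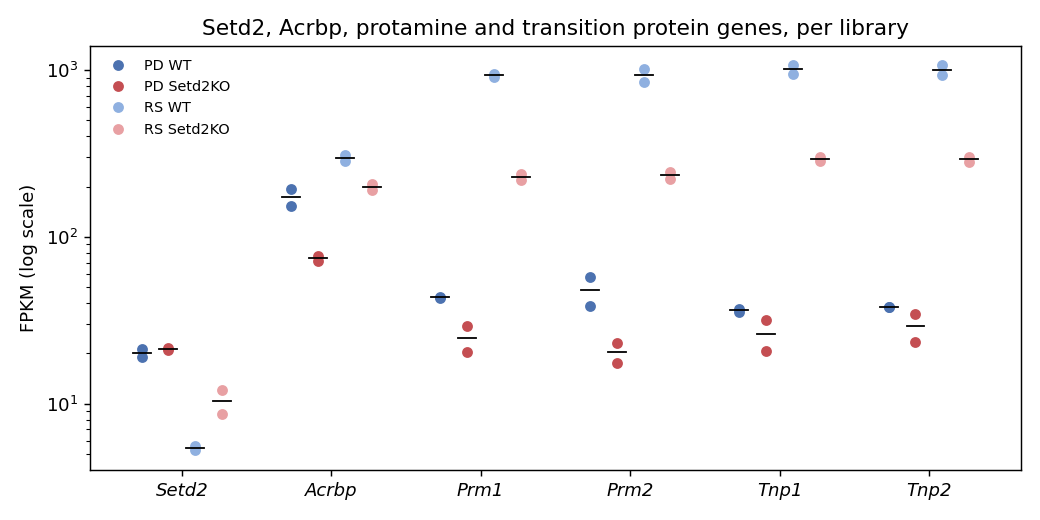
FPKM of Setd2, Acrbp, Prm1, Prm2, Tnp1 and Tnp2 (y axis, log scale) in each library, with 2 points per group and a bar at their mean. In RS the WT means of Prm1, Prm2, Tnp1 and Tnp2 are 927 to 1007 FPKM and the Setd2KO means 228 to 293 FPKM.

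In the spermatocyte libraries labelled Setd2KO the genes that fell most included Mxra8, a cell adhesion protein (chromosome 4, 155213789 to 155218211), from 27.7 ± 6.38 to 2.13 ± 0.666 FPKM. Slc25a10, the mitochondrial dicarboxylate carrier, went from 11.5 ± 2.22 to 0.662 ± 0.285 FPKM, and Slc2a8, a glucose transporter, from 15.6 ± 0.775 to 1.85 ± 0.352 FPKM. The gene that rose most was Tecr, an enzyme of very long chain fatty acid elongation (chromosome 8, 86095597 to 86118390), from 10.1 ± 0.737 to 59.2 ± 7.44 FPKM. Below it stood genes at far higher levels in round spermatids, such as Spaca1, an acrosomal membrane protein, which went from 3.88 ± 1.37 to 20.3 ± 9.21 FPKM and stood at 187 FPKM in RS WT. Fam122c rose by 1.99 relative to the all-gene median, Tmco5 by 1.78, and Kif2b, Fam209 and Tex33 by 1.67, 1.67 and 1.66. Abhd11 fell by 2.95, Chrne, a subunit of the acetylcholine receptor, fell by 2.5 and H2-K1, a class I histocompatibility antigen, fell by 2.44. Arc fell by 2.39, Fam89b fell by 2.01, Reep2 fell by 2.00 and the nucleotidase Nt5c fell by 1.99. Adjusted p of the genes of this paragraph ran from 5.54e-06 to 0.00103.

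Of 11452 genes tested, 3409 were higher and 721 lower in PD Setd2KO (limma, Benjamini-Hochberg adjusted p under 0.05), so 82.5% of the calls were higher. The median change of all genes was 0.19, and PD changes are therefore given relative to it, while p-values and counts test the deposited scale against 0. Upper-quartile scaling gave 2573 higher and 1307 lower (66.3% higher) and quantile normalization 1506 and 1787 (45.7%), so the predominance of higher calls depended on the scaling. The all-gene median was 0.13 without the first PD WT library and 0.26 without the second. It was 0.20 without the first PD Setd2KO library and 0.18 without the second. The first PD WT library also had the lowest sum of FPKM, 181915 against 219288 to 234791 in the other libraries.

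Transcripts specific to round spermatids were raised in the PD Setd2KO libraries as a class. For 517 genes of at least 20 FPKM in RS WT and at least 20-fold below that in PD WT, the median level was 1.92% and 2.77% of the RS level of the same genotype in the PD WT libraries and 13.1% and 7.67% in the PD Setd2KO libraries. Of these genes, 447 were called higher and 4 lower in PD, against 44 and 34 with the other cell type subtracted at a share estimated from these same genes, which brings their median near 0 by construction. The rule holds the mean WT level under 5%, so sets were also chosen in other ways after the values were seen. For 523 genes chosen on the first PD WT library alone the second read 2.77%, and for 553 genes at least 10-fold below RS WT in the mean of all 4 PD libraries the medians were 1.99% and 2.82% in WT and 13.2% and 7.74% in Setd2KO. Without the first Setd2KO library of each cell type 2302 of all genes were higher and 383 lower in PD, and with the other cell type subtracted at its estimated share 2630 and 774 (both settings chosen after seeing the data).

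**Figure D4:**
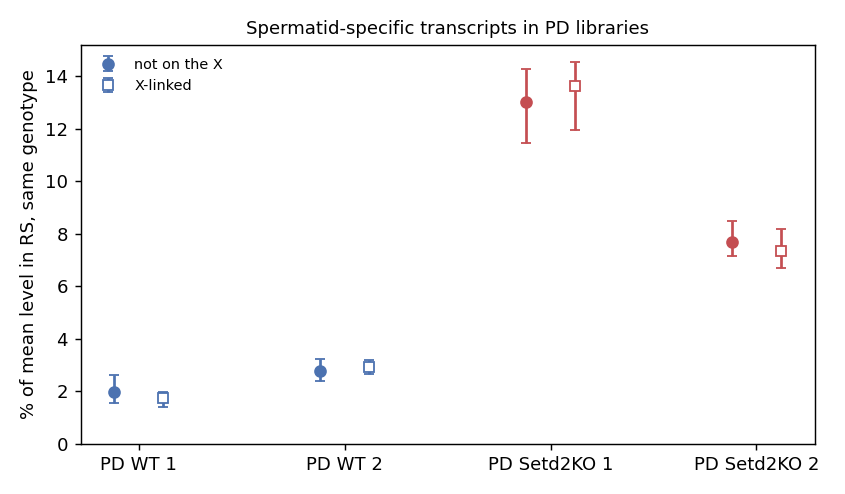
Level of spermatid-specific transcripts in each PD library as a percentage of their mean RS level in the same genotype (y axis), with medians as points and quartiles as bars, for 469 genes not on the X (filled) and 48 X-linked genes (open). Medians are 1.73% to 2.94% in the WT libraries and 7.33% to 13.7% in the Setd2KO libraries.

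Among the spermatid gene lists, members that passed in PD were mostly higher, as were 82.5% of all calls, beside the raised level of spermatid-specific transcripts given above. With the other cell type subtracted, at a share estimated from spermatid-specific genes, camera instead called lower protamines (adjusted p = 1.39e-06), elongating spermatids (9.36e-10), flagellum (0.000151), sperm-egg binding (0.00707), glycolysis (0.0435) and CatSper (0.0482). Negative values after subtraction were set to 0. In the first PD Setd2KO library the share taken off was 13.1%, above the median of Prm1, Prm2, Tnp1 and Tnp2 (11.3% of the RS Setd2KO level). In simulated data the share read 12.5% and 13.6% where 10% was added, so it can take off too much. These calls therefore do not show a fall in spermatocytes. In the acrosome list 16 of 31 genes rose and 2 fell (16 and 2 adjusted over the list alone), among them Spaca1 (1.89) and Tmem190 (1.58). For genes of histone to protamine exchange 10 of 23 rose and 0 fell (10 and 0), with Hils1, a spermatid linker histone, at 1.40 and H3f3b, which encodes histone H3.3, at 0.84. Post-meiotic transcription and mRNA storage regulators had 7 of 21 higher and 0 lower (7 and 0), such as Sox5 (0.94) and Kif17 (0.86). Of the sperm flagellum genes 8 of 36 rose and 3 fell (7 and 3), led by Ropn1 (1.64) and Spag6 (1.61). In sperm glycolysis 5 of 16 rose and 1 fell (5 and 1), led by the aldolases Aldoart2 (1.28) and Aldoart1 (0.78, a call lost without the first WT library). The direction of Aldoart1 was not settled, because with the other cell type subtracted its change was −0.10. Of the CatSper and sperm ion channel genes 6 of 16 rose and 1 fell (6 and 1), including Catsper4 (1.20) and Catsper3 (1.13). Manchette and head shaping had 3 of 22 higher and 2 lower (3 and 1), with Spag4 (1.24) and Sun5 (1.08). In sperm-egg binding and fusion 9 of 26 rose and 2 fell (9 and 2), led by the kinases Tssk4 (1.26) and Tssk2 (1.25). Of the multicopy sex-linked genes 2 of 6 rose and 0 fell (5 and 0), namely Slxl1 (1.47) and Uba1y (0.34, lost without the first WT library, adjusted p = 0.0600), both uncertain because reads of near-identical copies can be split. Of the markers of elongating and condensing spermatids 10 of 21 rose and 2 fell (12 and 2), and Fscb (1.20) moved on the deposited scale from 1.39 to 0.92 without the first Setd2KO library. In protamines and transition proteins 1 of 5 rose and 2 fell (1 and 3).

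In the meiotic and stress lists members that passed in PD were mostly higher as well, except in meiotic division, but so were 82.5% of calls over all genes, so this is not particular to these lists. In synaptonemal complex and recombination 13 of 28 genes rose and 2 fell (16 and 2 adjusted over the list alone), among them Tex15 (0.97) and Ccnb1ip1 (0.59). In meiotic division 2 of 21 rose and 4 fell (1 and 4), and the Aurora kinases Aurkc and Aurkb fell by 1.21 and 1.1. Of the piRNA pathway genes 7 of 18 rose and 0 fell (8 and 0), led by Asz1 (0.57) and Tdrkh (0.54). In H3K36 methylation writers, erasers and readers 7 of 25 rose and 1 fell (7 and 0), with Smyd2 at 0.43 (lost without the first WT library, adjusted p = 0.0619) and the DNA methyltransferase Dnmt3b at 0.42. Of the p53 targets and apoptosis genes 6 of 13 rose and 2 fell (9 and 3), with Perp at 0.61 and Bak1 at −0.70 (lost without the first Setd2KO library, 0.0850). In the unfolded protein and integrated stress response 3 of 13 rose and 2 fell (3 and 2), with asparagine synthetase Asns at 1.09 and Atf4 at 0.30, a call lost without any 1 of 3 libraries (0.0555 to 0.155). Of the immediate early and heat shock genes 6 of 10 rose and 0 fell (6 and 0), led by Hspb1 (0.86) and Jund (0.67). In housekeeping genes 2 of 15 rose and 1 fell (2 and 1), with Gapdh at −0.99 and Sdha at 0.48, which did not pass (adjusted p = 0.0592). No list passed camera in PD, where the lowest adjusted p was 0.0684, for protamines and transition proteins (0.909 with an estimated correlation). Fry, which tests each list against no change on the deposited scale, passed p53 targets, immediate early genes and spermatogonia (fry adjusted p = 0.01335 each). It also passed the piRNA, histone exchange and H3K36 lists (0.0283 each) and the synaptonemal complex (0.0313). The all-gene median of 0.19 was not taken off for fry. The list median relative to all genes and the camera direction had opposite signs for post-meiotic regulators (−0.04), sperm-egg binding (0.02) and housekeeping (0.03). Without the first Setd2KO library camera called protamines lower (0.00339), meiotic division lower (0.0201), and immediate early genes and spermatogonia higher (0.0201 each). Without the second it called acrosome (0.0224) and elongating spermatids (0.0196) higher, and without the second WT library protamines lower (0.00784).

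In the round spermatid libraries labelled Setd2KO the largest falls included Spatc1, a centrosomal protein of spermatids (chromosome 15, 76098519 to 76123002), from 23.8 ± 0.977 to 1.70 ± 0.0226 FPKM. The glucose transporter Slc2a8 went from 12.3 ± 0.831 to 0.887 ± 0.103 FPKM and the receptor subunit Chrne from 21 ± 1.81 to 2.12 ± 0.108 FPKM, both lower in PD as well. Among the rises, Cd24a, a glycosylated surface protein (chromosome 10, 43298975 to 43304071), went from 1.49 ± 0.164 to 16.6 ± 0.0301 FPKM, and Tecr from 10.0 ± 1.07 to 50.7 ± 4.96 FPKM, close to its rise in PD. Log2 changes were −3.20 for Spatc1, −2.82 for Slc2a8 and Chrne, −2.70 for the taste receptor Tas1r1, −2.65 for Alkbh7, −2.46 for Mxra8 and −2.31 for Nt5c. They were 2.82 for Cd24a, 2.41 for Tigd2, 2.30 for the matrix proteoglycan Dcn, 2.23 for Tecr, 2.15 for the smooth muscle light chain Myl9, 2.13 for Fgf12, 2.00 for the Notch target Hey1, 1.93 for Fcgr3 and 1.73 for Ppfibp2. Rnls rose by 2.10 (adjusted p = 0.00302), a value that went to 1.17 without the first RS WT library, and the other genes of this paragraph had adjusted p from 1.07e-07 to 2.51e-05.

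Of the 11452 genes, 2390 were higher and 2499 lower in RS Setd2KO, so 48.9% of the calls were higher, and the all-gene median change was 0.02. Upper-quartile scaling gave 3030 and 2528 (54.5% higher) and quantile normalization 3008 and 2663 (53%). Leaving out the first RS WT library gave 1278 and 1671, and leaving out the first RS Setd2KO library 1499 and 1610.

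Late spermatid genes fell together in RS Setd2KO, and genes of meiotic division rose, in the same libraries in which Sertoli cell markers (6 of 6) were higher, while smooth muscle genes went both ways, Acta2 (2.01) and Myh11 (1.38) up and Actg2 (−1.74) down. In protamines and transition proteins 0 of 5 rose and 5 fell (0 and 5 adjusted over the list alone), with a median change of −1.78 (camera, adjusted p = 0.00115, and adjusted p = 0.878 with an estimated correlation). Of the markers of elongating and condensing spermatids 0 of 21 rose and 17 fell (0 and 18), with a median of −0.88 (7.63e-07, and adjusted p = 0.878 with an estimated correlation). That list shares Prm2, Prm3 and Tnp2 with the protamine list, and Spem1, which acts in late sperm head formation, fell by 1.5 and the mitochondrial capsule gene Smcp fell by 1.27. In sperm-egg binding and fusion 3 of 26 rose and 11 fell (3 and 11), with a median of −0.41 (0.0355, and adjusted p = 0.878 with an estimated correlation). Sperm-egg binding and fusion did not pass fry (fry adjusted p = 0.145). Tmem95, a sperm membrane protein needed for fertilization, fell by 1.96, the chaperones Calr3 and Pdilt fell by 1.40 and 1.37, and Rnase10 rose by 1.39. In meiotic division 12 of 21 rose and 1 fell (13 and 2), with a median of 0.52 (0.00356, and adjusted p = 0.878 with an estimated correlation). The kinase Nek2 rose by 1.56, the meiotic transcription factor Mybl1 by 1.42, Cdk1 by 1.31 and the cohesin protector Sgol2a by 1.20. Of the immediate early and heat shock genes 7 of 10 rose and 1 fell (8 and 1), with a median of 0.51 (0.00409, and adjusted p = 0.878 with an estimated correlation). Hspb1 rose by 1.53, Fos by 1.41, Junb by 0.84 and Jun by 0.65. The sperm-egg call was lost without the first or second PD WT library (adjusted p = 0.0850 and 0.0852), the first RS Setd2KO library (0.0590) or the first RS WT library (0.0553), and with quantile normalization (0.0925) or a pseudocount of 0.1 FPKM (0.0563).

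The remaining gene lists did not pass camera in RS. In the acrosome list 5 of 31 rose and 6 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.792), with Zp3r at −0.77 (lost without the first Setd2KO or the first WT library, adjusted p = 0.192 and 0.206) and Gopc, which sorts proacrosomal vesicles, at 0.65. In histone to protamine exchange 2 of 23 rose and 6 fell (1 and 6; 0.651), with the histone variant H2afb1 at −1.18 and the kinase Tssk6 at −1.06. Post-meiotic regulators had 5 of 21 higher and 4 lower (5 and 4; 0.490), with the deadenylase Cnot7 at 0.84 and Pabpc2 at 0.86 (lost without the first WT library, 0.0678). Sperm flagellum had 2 of 36 higher and 7 lower (1 and 6; 0.351), with Smcp at −1.27 and the dynein chain Dnaic2 at 0.87. Sperm glycolysis had 2 of 16 higher and 1 lower (2 and 1; 0.564), with the glucose transporter Slc2a3 at 1.15 and Cyct at 0.74 (lost without the first Setd2KO or the second WT library, 0.0572 and 0.0863). CatSper and ion channels had 0 of 16 higher and 4 lower (0 and 2; 0.252), with Catsper1 at −1.07, which went to −0.61 without the first Setd2KO library, and Atp1a4 at −0.88 (lost without that library, 0.0713). Manchette and head shaping had 2 of 22 higher and 5 lower (2 and 5; 0.339), with Spem1 and with Sun5 at −0.69, a call lost without any 1 of 5 libraries (0.0549 to 0.320). Multicopy sex-linked genes had 1 of 6 higher and 2 lower (1 and 2; 0.651), with Uba1y at −0.83 and Slxl1 at 0.83, lost without any 1 of 4 libraries (0.0624 to 0.139).

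Synaptonemal complex genes had 2 of 28 higher and 9 lower in RS (2 and 9 adjusted over the list alone; camera adjusted p = 0.327), with Syce2 at −1.51 and the cohesin Rec8 at −1.16 against Hormad1 at 1.30 and Sycp3 at 1.13. The piRNA pathway had 5 of 18 higher and 1 lower (4 and 1; 0.327), with Mael at 0.63, lost without any 1 of 6 libraries (adjusted p = 0.0548 to 0.158). H3K36 writers, erasers and readers had 3 of 25 higher and 3 lower (1 and 3; 0.883), with the methyltransferase Whsc1l1 at −0.72. The p53 list had 4 of 13 higher and 0 lower (4 and 0; 0.324), with Gadd45b at 0.70 and Ccng1 at 0.58, and it passed fry (fry adjusted p = 0.0168). The unfolded protein response had 2 of 13 higher and 0 lower (2 and 0; 0.874), with the chaperone Dnajb9 at 0.50 (lost without the first Setd2KO or the first WT library, 0.0712 and 0.103) and Hspa5 at 0.36, which did not pass (0.0944). Housekeeping genes had 3 of 15 higher and 1 lower (0 and 0; 0.505), with Sdha at 0.69 and Rpl13a at −0.56, calls lost without any 1 of 3 libraries (0.130 to 0.352) and any 1 of 4 (0.0906 to 0.154). The list median and the camera direction had opposite signs for histone to protamine exchange (0.07) and for the unfolded protein response (−0.15).

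**Figure D5:**
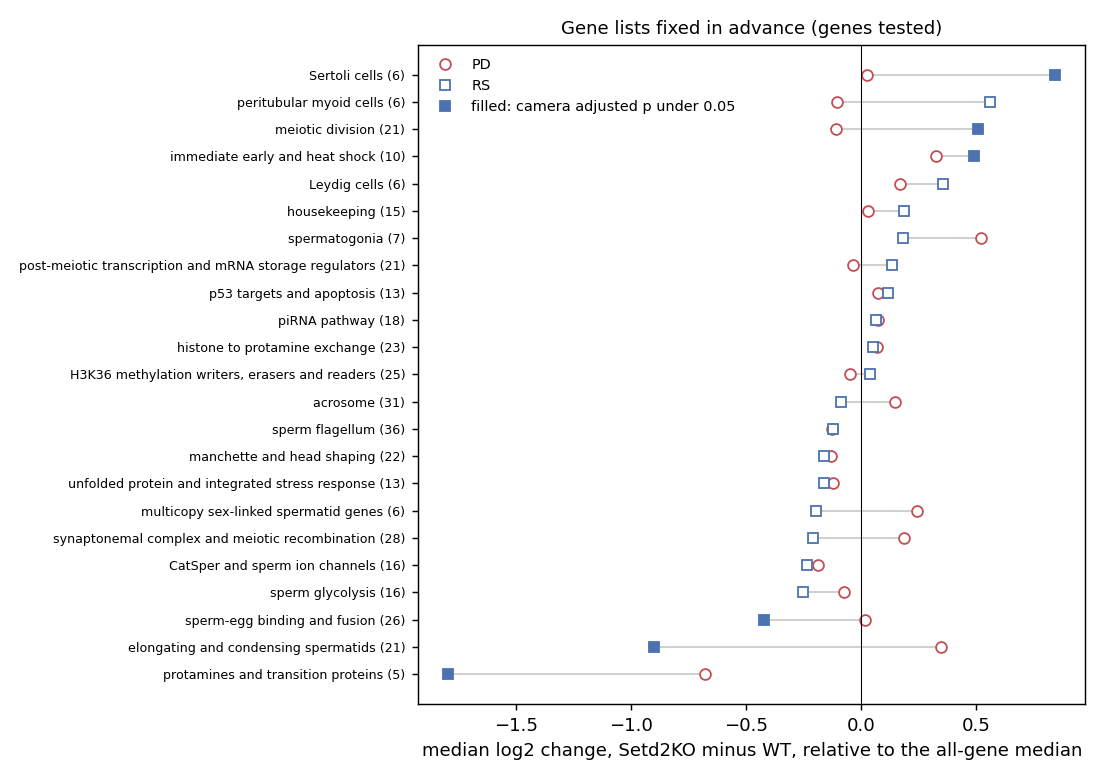
Median log2 change of each list in Setd2KO relative to the all-gene median (x axis) in PD (circles) and RS (squares), with list names and numbers of tested genes on the y axis and filled symbols where camera adjusted p is under 0.05. No PD symbol is filled, and in RS the filled ones include elongating spermatids (adjusted p = 7.63e-07) and Sertoli cells (0.0019).

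Markers of other testis cells were read to weigh what else was in the sorted fractions. In RS, Sertoli cell markers, of the somatic cells that nurse the germ line, had 6 of 6 higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 0.0019, and adjusted p = 0.878 with an estimated correlation). Inha went from 1.06 to 3.62 FPKM, Clu from 3.21 to 6.96, Cst12 from 1.28 to 3.21 and Ctsl from 0.799 to 2.22. Peritubular myoid markers had 4 of 6 higher and 1 lower (4 and 1; 0.252), with smooth muscle actin Acta2 at 2.01, Myh11 at 1.38 and Actg2 at −1.74. The myoid list passed fry (fry adjusted p = 0.04785). Leydig cell markers had 3 of 6 higher and 1 lower (3 and 1; 0.339), with Insl3 at 0.77 (lost without any 1 of 4 libraries, adjusted p = 0.0882 to 0.344) and Akr1cl at 0.74 (lost without the second Setd2KO or the second WT library, 0.0697 and 0.101). Spermatogonia markers had 3 of 7 higher and 2 lower (3 and 2; 0.490), with the repressor Id4 at 0.76 and Uchl1 at −0.76. Car2, a member of the elongating and condensing spermatid markers, stood at −1.63.

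In PD, spermatogonia markers had 5 of 7 higher and 0 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.176), with Stra8, the retinoic acid target of meiotic entry, at 1.25 and Uchl1 at 0.55 (lost without the second Setd2KO or the first WT library, 0.0584 and 0.0772). Sertoli markers had 1 of 6 higher and 0 lower (1 and 0; 0.721), with Inha at 0.43. Leydig markers had 2 of 6 higher and 0 lower (2 and 0; 0.725), namely Insl3 at 0.74 and Akr1cl at 0.41, each lost without any 1 of 3 libraries (0.0822 to 0.145 and 0.143 to 0.245). Myoid markers had 1 of 6 higher and 1 lower (1 and 1; 0.425), with the kinase Mylk at −0.80 and Myh11 at 0.14, lost without any 1 of 3 libraries (0.102 to 0.219). The interferon response, macrophages, and erythrocytes and endothelium had fewer than 3 tested genes and no list test. Mx1, an interferon-induced GTPase, stood at −0.15 in PD (adjusted p = 0.725) and fell by 0.37 in RS. Lyz2 passed in neither (0.211 and 0.268), Adgre1 fell by 0.34 in RS (lost without the first Setd2KO or the second WT library, 0.0731 and 0.120), and Vwf fell by 0.47 in RS, while Tek passed in neither (0.241 and 0.224).

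The step from spermatocyte to round spermatid was read in each genotype. In WT, Acrv1, an acrosomal antigen, went from 3.44 ± 0.827 to 210.1 ± 39.2 FPKM, and the testis linker histone Hist1h1t went from 681 ± 120.2 to 9.33 ± 0.805 FPKM. Relative to the all-gene median Acrv1 rose by 5.78, Tex33 by 5.76, Fam71e2 by 5.75, Ropn1 by 5.72 and Gtsf1l by 5.65. Hist1h1t fell by 5.82, the testis histone Hist1h2ba fell by 5.77, Stox1 fell by 4.82, Tex101 fell by 4.26 and Hist1h2aa fell by 4.20. In WT 4117 genes were higher and 5352 lower in RS (all-gene median −0.21), and in Setd2KO 3921 and 5553 (−0.27). Prm1 rose by 4.60 in WT and 3.44 in Setd2KO, Prm2 by 4.48 and 3.74, Tnp1 by 4.97 and 3.74, Tnp2 by 4.89 and 3.58, and Acrbp by 1.00 and 1.67. With the other cell type subtracted, the Setd2KO minus WT difference of this rise turned to 1.48 for Prm1 (limma, adjusted p = 0.123), 1.91 for Tnp1 (0.00580) and 1.61 for Tnp2 (0.0261). In the PD Setd2KO libraries the median of Prm1, Prm2, Tnp1 and Tnp2 (11.3% and 7.77% of RS Setd2KO) lay close to the share taken off. The turned values therefore depend on that share, and the smaller rise of these genes in Setd2KO is not settled. Acrv1 rose by 3.52 in Setd2KO, whereas Hist1h1t fell by 5.68, close to its WT fall. In PD Setd2KO, spermatid-specific transcripts stood at 13.1% and 7.67% of the RS Setd2KO level, which limits the rise that such genes can show. A smaller rise in Setd2KO therefore does not by itself show a weaker rise in the cells.

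The Setd2KO effect differed between the cell types for many genes. Spatc1 fell further in RS than in PD, with a difference of −2.51 relative to the all-gene median (adjusted p = 2.52e-05). Sec23a, a vesicle coat protein (−2.33), and Fbxo15 (−2.25) were called higher in PD and lower in RS (Sec23a in PD lost without the second Setd2KO library, adjusted p = 0.0524), Znrf4 (−2.23) was called lower in RS only, and Tmem190 (−2.21) was called higher in PD and did not pass in RS (adjusted p = 0.143). Ndc80, a kinetochore protein, differed by 1.81, Gsn by 1.78, Pxt1 by 1.74 and Aurkb by 1.72, and Rnls by 1.99, a call lost without any 1 of 6 libraries (0.0558 to 0.174). Of 11452 genes, 889 were more positive in RS and 3126 more negative (22.1% positive), with an all-gene median of −0.16. Upper-quartile scaling gave 1855 and 2618 (41.5%) and quantile normalization 2327 and 2074 (52.9%), so the excess of negative differences depended on the scaling. Without the first PD WT library the counts were 1584 and 2756, without the first RS WT library 517 and 2308, and without the first RS Setd2KO library 575 and 2351.

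Genes that changed in both cell types mostly changed alike. Of the genes tested 952 were higher in both against 711.4 expected if independent, 361 were lower in both against 157.3, 556 were higher in PD and lower in RS against 743.9, and 51 the reverse against 150.5. Tecr was among 16 genes at least 2-fold higher in both, and Mxra8, Slc2a8, Chrne, Nt5c, Abhd11 and Slc25a10 were among 47 at least 2-fold lower in both. Setd2KO effects in PD and RS correlated at r = 0.217 (Spearman 0.176, covariance 0.0466). The simulated r without an effect in either cell type was −0.00179, near 0 by construction because these contrasts share no library. The RS minus PD change in WT correlated with the Setd2KO effect in RS at r = −0.382 (Spearman −0.365). Both use the RS WT libraries. With noise drawn separately for each gene and library, this sharing gave a simulated r of −0.0414 and a covariance of −0.00967 against the covariance of −0.322 seen. A deviation common to both RS WT libraries would also make r negative and was not simulated. The draws therefore do not bound what the shared libraries can give.

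Genes that lost their peak were then compared with other genes. Mxra8 and Slc2a8 fell with the mark, but the 8252 tested genes with a WT peak and no Setd2KO peak in PD had a median change of 0.160, against 0.192 for random gene sets of matched expression drawn from all tested genes. The 2706 tested autosomal genes without a PD WT peak had a median of 0.27. In RS the 7686 genes that lost a peak had a median of 0.0219 against 0.0144 for random genes, and the 2953 autosomal ones without a WT peak −0.0552. The observed value stood at the 0.0 percentile of random gene sets in PD and at the 99.2 percentile in RS, where it went to 3.51 without the first Setd2KO library. These percentiles take genes, not libraries, as the unit, and each group had 2 libraries. The 8252 and 7686 genes that lost a peak were most of the 11452 tested genes. The random sets were drawn from that same pool, so they shared many of these genes. The percentiles therefore do not measure the spread between libraries, and the differences between the medians were small. Random sets of autosomal genes only, a comparison added after the data were seen, had medians of 0.184 in PD and 0.0081 in RS. In PD 23.9% of genes with a peak were higher and 7.14% lower, against 43.7% and 4.55% of those without, and in RS 19.1% and 19.6% against 24.0% and 28.9%. These shares varied with expression: in the lowest of 4 expression classes 37.5% with a peak were higher in PD against 33.3% without, and in the highest 12.6% against 60.8%. In RS the highest class had 20.5% higher with a peak against 13.5% without, and the lowest 15.1% against 34.2%. The classes were set on mean expression over PD and RS libraries together, so the highest can hold genes high in RS and low in PD. Of 517 spermatid-specific genes, 447 were called higher in PD Setd2KO. Their part in the classes without a peak was not tested. The PD shares therefore do not by themselves tie a lack of the mark to a rise in spermatocytes.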

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

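The 13 tests of explanations for the first 3 patterns were chosen only after the results were seen, whereas the difference between effects was a planned contrast. Also chosen afterwards were the settings that subtract the other cell type or leave out the first Setd2KO libraries.

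Spermatid-specific transcripts were higher in the PD Setd2KO libraries than in PD WT. If round spermatids or their RNA were in those libraries, X-linked and autosomal spermatid transcripts would be raised alike, and the X-linked median was 13.653% of the RS Setd2KO level in the first library, inside the autosomal quartiles of 11.4% to 14.3%, and 7.33% in the second, inside 7.15% to 8.47%. This is consistent with spermatid RNA as a candidate explanation. The authors' scaling is argued against as the whole cause, because under quantile normalization the lower quartile stayed 0.4267 above the all-gene median (362 genes higher, 7 lower), and more under upper-quartile scaling (427 and 5), but a part in the size is left open, because the median went to 0.7614 and the lower quartile of 0.431 missed a bound of 0.5 that was itself set after the results were seen. Earlier onset in Setd2KO spermatocytes is argued against where genes start 1 by 1 at different levels, because 94.67% to 100% of autosomal and of X-linked genes lay within 1.5-fold of the median share in each library, above a bound of 90% that was also set afterwards, but a shared onset of the whole set is left open, because Prm1, Prm2, Tnp1 and Tnp2 had a median of 11.324% in the first library, just under the lower quartile of 11.5%, and 7.77% in the second, inside the quartiles.

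Late spermatid genes were lower and meiotic division genes higher in RS Setd2KO. Pachytene and diplotene spermatocytes are argued against as the cause of both, because if they were added at 2.51 points, the highest upper quartile of PD-specific transcripts in RS Setd2KO minus the lowest lower quartile in RS WT, they would change the 21 meiotic division genes by a median of 0.0218 (upper quartile 0.09) against 0.52 seen (lower quartile 0.18), and the elongating markers by −0.03, while later meiotic cells were not measured. The authors' scaling is argued against too, because elongating spermatid markers had a median of −0.8393 under upper-quartile scaling. Other cells in place of spermatids are left open, because Sertoli markers (median 0.86) were higher while smooth muscle genes went both ways (Acta2 2.01, Actg2 −1.74), and 499 other spermatid-specific genes fell by less than the elongating markers, with a median of −0.4882, but their lower quartile of −0.79 reached the upper quartile of those markers. Fewer late spermatids among the sorted cells could lower these markers together, and the upper quartile of −0.7805 leaves that open against a lower output per cell.

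The WT lists carried no peak on the X or the Y. A low RNA level is argued against in RS, where 134.28 of 169 X-linked genes of at least 5 FPKM would have carried a peak at the autosomal share and 0 did. That share came from all autosomal genes at that level, whether or not they were expressed in PD. Autosomal genes far higher in RS than in PD were not compared separately. Such genes went both ways: Kif2b (256 FPKM in RS WT) had no RS WT cover and Spz1 (288 FPKM) had 100%. The test therefore does not cover the time at which a gene is first transcribed. In PD a low RNA level is argued against, because 12.71 of 16 X-linked genes of at least 1 FPKM would have carried a peak and 0 did. Low transcription is left open there, because with the spermatid share taken off only 6 of these genes stayed at 1 FPKM, with 4.74 expected to carry a peak and 0 seen, and RNA can outlast transcription. Had the authors left out X and Y peaks from all lists, none would hold an X peak, but the RS Setd2KO list held 13. Leaving them out of some lists only, such as those of WT, is left open, because it would allow those 13 peaks.

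Genes whose Setd2KO effect differed between the cell types numbered 4015, and values below are RS minus PD relative to the all-gene median. Lists that differed were protamines and transition proteins (−1.13), meiotic division (0.85), elongating and condensing spermatids (−1.3), Sertoli cells (0.74) and peritubular myoid cells (0.82), with camera adjusted p of 0.0388, 5.02e-06, 9.48e-07, 0.0015 and 0.00899 (adjusted p = 0.911 with an estimated correlation).

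Among spermatid genes the effect was more negative in RS for Prm1 (−1.06), Tnp1 (−1.13), Tnp2 (−1.21), Prm3 (−1.69), Spaca1 (−2.0), Tmem190 (−2.21), Zp3r (−1.85), Acrv1 (−2.17), Hils1 (−1.83), H3f3b (−0.81, lost without any 1 of 5 libraries, adjusted p = 0.0618 to 0.133), H2afb1 (−0.97), Tssk6 (−1.17), Sox5 (−1.14) and Kif17 (−1.47). A more negative difference can come from a rise in PD as well as from a fall in RS. In PD 447 of 517 spermatid-specific genes were called higher, and Tmem190 was called higher there but did not pass in RS. With the other cell type subtracted, the difference on the scale so made turned to 1.48 for Prm1 (adjusted p = 0.123), 1.91 for Tnp1 (0.00580) and 1.61 for Tnp2 (0.0261), so its direction is not settled for these genes. It was more negative as well for Ropn1 (−2.19), Spag6 (−2.03), Smcp (−1.46), Aldoart2 (−1.7), Aldoart1 (−1.23), Catsper1 (−1.76), Catsper3 (−1.63), Catsper4 (−1.69), Atp1a4 (−1.48), Spag4 (−1.81), Sun5 (−1.8), Spem1 (−1.03), Tssk2 (−1.68), Tssk4 (−1.89), Tmem95 (−1.95), Calr3 (−1.59), Pdilt (−2.14), Fscb (−1.37) and Uba1y (−1.2). Others were Fam122c (−0.91, lost without any 1 of 6 libraries, 0.0680 to 0.113, and 0.64 with the other cell type subtracted), Tmco5 (−1.97), Kif2b (−1.95), Fam209 (−2.01), Tex33 (−2.1), Fam71e2 (−1.95), Gtsf1l (−2.04), Spatc1 (−2.51), Tas1r1 (−2.07), Alkbh7 (−1.53), Sec23a (−2.33), Fbxo15 (−2.25) and Znrf4 (−2.23).

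Among meiotic and stress genes and markers of other cell types it was more negative for Actg2 (−1.8), Car2 (−1.16), Tex15 (−1.47), Ccnb1ip1 (−0.62), Syce2 (−1.54), Rec8 (−1.56), Asz1 (−0.88), Tdrkh (−0.74), Smyd2 (−0.97), Whsc1l1 (−0.5), Perp (−0.51), Asns (−1.27), Stra8 (−0.72), Uchl1 (−1.35) and Vwf (−0.52). Calls lost without single libraries were those of Dnmt3b (−0.29, any 1 of 5, adjusted p = 0.0762 to 0.105), Atf4 (−0.55, any 1 of 4, 0.0678 to 0.112), Hist1h2aa (−0.54, any 1 of 4, 0.0586 to 0.0865), and Jund (−0.41) and Mx1 (−0.26), each without 1 library (0.0639 and 0.0600).

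The effect was more positive in RS for Aurkb (1.72), Ndc80 (1.81), Nek2 (1.52), Mybl1 (1.42), Cdk1 (1.4), Sgol2a (1.4), Pxt1 (1.74), Dnaic2 (1.29), Slc2a3 (1.65), Rnase10 (1.31), Gadd45b (0.86), Jun (0.79), Inha (0.7), Myh11 (1.21, but −0.20 with voom on recovered reads, adjusted p = 0.882), Acta2 (1.85), Gsn (1.78) and Myl9 (1.69). It was likewise for Cd24a (1.47), Tigd2 (1.32), Fgf12 (1.27), Hey1 (1.25), Ppfibp2 (1.42), Slc25a10 (1.28), H2-K1 (1.03) and Arc (1.45). Calls lost without single libraries were those of Setd2 (0.90, any 1 of 5, adjusted p = 0.0524 to 0.0943), Aurkc (0.92, any 1 of 5, 0.0612 to 0.0953), Hormad1 (0.89, any 1 of 4, 0.0561 to 0.127), Mxra8 (0.89, any 1 of 6, 0.0663 to 0.179), Abhd11 (0.75, any 1 of 7, 0.0764 to 0.142), Dcn (1.13, any 1 of 6, 0.0518 to 0.123) and Rnls (1.99, any 1 of 6, 0.0558 to 0.174). Others were Hspb1 (0.63, any 1 of 4, 0.0705 to 0.144), Fos (0.83, any 1 of 2, 0.0633 to 0.0710), Clu (0.85, any 1 of 4, 0.0705 to 0.104), Cst12 (0.83, any 1 of 3, 0.0711 to 0.103) and Ctsl (0.75, any 1 of 4, 0.0678 to 0.0927).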

How the results depend on the processing

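Settings that changed a result are given here, and the cause was not tested unless said. Tests chosen only after the results were seen were voom on recovered reads, genes of 1 length only, subtraction of the other cell type, leaving out the first Setd2KO library of each cell type, and random sets of autosomal genes only. A filter at 5 FPKM gave 2566 changed genes in PD, 2998 in RS, 6262 and 6189 between cell types in WT and Setd2KO, and 2452 for the difference between effects, where by construction fewer genes are tested. Adding a 2-fold threshold gave 508, 626, 5343, 5232 and 1230, fewer by construction, and the rise of Setd2 in RS (0.81) then missed the threshold. Without the first Setd2KO library of each cell type the counts were 2685 in PD, 2953 in RS and 2401 for the difference. Leaving out a single library gave 2537 and 2610 in PD for the first and second Setd2KO libraries and up to 4575 (second PD WT), and in RS 2949 (first WT), 3109 (first Setd2KO) and up to 5719 (second PD WT). With the replicate number as a replicate block the totals were 3894 in PD, 4695 in RS, 9458 and 9453 between cell types and 3822 for the difference, so block and no block differed little. The replicate numbers did not pair across groups (r of deviations −0.309 to 0.0682).

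Setd2 in PD, on the deposited scale, was −0.0598 under upper-quartile scaling, −0.0446 under quantile normalization, and 0.14 and −0.0018 without the first and the second PD WT library. Subtracting the other cell type turned the sign of Aldoart1 (−0.10), Prm3 (−0.0837) and Atp1a4 (−0.50) in PD and of the difference between effects for Fam122c (0.64), Prm1 (1.48), Tnp1 (1.91) and Tnp2 (1.61). Quantile normalization turned Ccng1 in PD (−0.0003), and voom on recovered reads turned the difference for Myh11 (−0.20).

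Gene lists called in PD, 0 as planned, numbered 4 with a pseudocount of 0.1 FPKM, 1 with no filter, 1 with a replicate block, 1 without the second PD WT library, 3 without the first and 1 without the second PD Setd2KO library, 3 without the first Setd2KO libraries, 1 with voom and 7 with the other cell type subtracted, 6 of them lower (protamines, flagellum, CatSper, glycolysis, sperm-egg binding and meiotic division) and recombination higher. In RS, where 4 were called, a pseudocount of 0.1 FPKM and quantile normalization left 3, a filter at 5 FPKM 2 and an estimated correlation 0, and no filter gave 5. Sperm-egg binding and fusion was lost with that pseudocount (adjusted p = 0.0563), quantile normalization (0.0925), the filter at 5 FPKM (0.0728) and without the first Setd2KO libraries (0.0509), and immediate early genes with the filter at 5 FPKM (0.271). Marker lists called in PD, 0 as planned, numbered 1 without either PD Setd2KO library or without the first of each cell type, and 2 with subtraction. In RS, where 2 were called, no filter gave 4, a filter at 5 FPKM 1 and an estimated correlation 0.

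The correlation of the RS minus PD change in WT with the Setd2KO effect in RS was −0.304 with a pseudocount of 0.1 FPKM, −0.279 and −0.461 without the first and second RS Setd2KO library, and −0.326 with subtraction. That of the effects in PD and RS was 0.265 and 0.169 without the first and second PD Setd2KO library and 0.290 and 0.147 without those of RS.

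Among peaks of at least 1000 bases the WT list exceeded Setd2KO 7026 times in bases and 1520 times in number in PD, and 200420.4 and 32540 times in RS, where 1 Setd2KO peak was left. Merging peaks gave ratios of number of 18.5 and 5.28. WT peaks with 50% of their length under Setd2KO peaks made up 0.011% in PD and 0.006% in RS, and among peaks of at least 1000 bases 0.01% and 0.0% overlapped. Reciprocal overlap of 50% held for 42.7% of PD WT and 54.9% of RS WT peaks, and 87.1% of PD WT peaks of at least 1000 bases overlapped RS WT. With cover of 20% required, 93.9% of genes with and 15.1% without a peak reached 1 FPKM in PD, and 82.7% and 24.4% in RS. The excess of the median change of genes that lost peaks in RS over random sets was 0.0048 under upper-quartile scaling, 0.0060 without the first RS WT library, 0.0204 without the second RS Setd2KO library and −0.0056 without the first RS Setd2KO library, and 0.0138 against autosomal genes only.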

Other observations

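The PD Setd2KO peaks were looked at by gene after the values were seen, because the longest of them lay over Kif2b, a kinesin gene that is far higher in spermatids. Of 468 autosomal spermatid-specific genes, 40 had a PD Setd2KO peak (8.55%, exact 95% interval 6.18% to 11.5%), against 192 of 10616 other genes (1.81%, 1.56% to 2.08%). In RS Setd2KO the shares were 19 (4.06%) and 596 (5.61%). Of these spermatid-specific genes at least 30% of the gene was covered for Kif2b (85.5%), Ccdc182 (75.8%), Ddi1 (53.3%), Zdhhc25 (42.8%), Nkx2-6 (42.1%), Spz1 (38.1%), Fam170b (37.0%) and Ccdc54 (36.5%). Apart from Spz1, with 100% cover in PD WT and RS WT, these named genes had no cover in PD WT, RS WT or RS Setd2KO. Their PD Setd2KO peaks therefore matched no peak of the spermatid lists. Genes outside that set with such cover were Actl7b (38.9%), Gykl1 (38.0%) and Fzr1 (31.3%), each with at least 96.5% cover in PD WT. With 1 library per group this has no replicate check.

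Genes at least 2-fold changed alike in both cell types were also read after the values were seen. Of 47 lower in both, which include the glucose transporter Slc2a8, 38 (80.9%) had WT peaks in both cell types, against 4 of 16 higher in both (25%), which include Tecr, and 70.6% of autosomal tested genes. Peaks followed WT expression: in PD WT 28.5% of autosomal genes of 0.1 to 1 FPKM had a peak, against 94.9% at 5 to 20 FPKM. A gene that falls 2-fold must be expressed in WT and a gene that rises need not be, so the contrast is partly set by the choice of genes. The 47 and 16 genes were not limited to autosomes. Of 219 tested genes within 20 megabases of Setd2, 28 (12.8%) changed alike in both, against 11.5% of all tested genes.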
